A study of Mus musculus with 2 samples.

How the data were processed

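The series holds 1 ERRγ chromatin immunoprecipitation (ChIP) library and 1 input library, both from neurons derived from ES-D3 mouse embryonic stem cells, and the labels give no replicate of either. ERRγ is an orphan nuclear receptor, and the input is DNA from the same kind of cells sequenced without an antibody step. Reads were aligned with Bowtie to mm9 and peaks were called with HOMER, per the submitters' processing notes. Versions and settings are not given in the sources used here.

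The alignment files list 1 aligned read per line with its strand, position, 42-base sequence and mismatches, and the authors deposited in them a count of the other places where each read matched, which was above 0 for 151 ChIP reads and 140 input reads. The deposited peak list gives, per the file headers, a peak score, a false discovery rate (a p-value type of measure, 0 for every peak), the number of tag positions, and counts of ChIP tags in the 116 bp peak, of ChIP tags in 10 kb and of input tags in the peak. Scores and counts of that list are the authors' and were used to describe and rank peaks. All coordinates are those of the deposited files, in mm9.

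For each library at most 1 tag per position and strand was kept, so that copies made by PCR counted once. The distance between strands with the most read pairs, smoothed by a running mean over 5 distances and searched from 60 to 300 bp, plus 1 bp gave a fragment length of 122 bp for the ChIP and 121 bp for the input, and tags were moved by 61 bp towards their 3′ end. Kept tags were counted in 200 bp around each peak centre and scaled to each library's total of kept tags. The fold at a peak was ChIP over input, with the input taken as 3 tags where it was lower. For a named peak with at least 1 input tag the ratio of the counts is given with an exact conditional binomial interval (95%). For a named peak with 0 input tags the fold against the floor of 3 tags is given, without an interval. Shares have exact binomial intervals. Intervals and floors cover counting error only, and no difference between the libraries has a replicate check.

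The mm9 sequence was read from the alignments themselves, with each mismatched base set back to the reference base that Bowtie recorded. This gave 675190337 bases. In 714384820 repeat sightings of a base, 0 gave a different reference base. The ERR response element was TNAAGGTCA, with any base at N, on either strand within 100 bp of the peak centre, beside windows of equal size centred 1 kb to either side. Reads covered 96.8% of the bases at peaks but 44.1% and 42.5% in the windows 1 kb before and after, so rates are also given per covered start position.

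Reads more than 1 kb from any peak were searched for all 8-mers. The log2 ratio of ChIP to input reads of each 8-mer was set against the median of 8-mers with the same GC and CpG counts, over 32887 8-mers with at least 100 reads in each library, and 8-mers were ranked by this excess divided by its SE. Since that matches the 8 bases only, reads with GCATGCGC or another chosen 8-mer were also compared with reads without that 8-mer. This used 40 classes of GC and 13 of CpG content of the 122 bp fragment, with at least 61 bases of known sequence. Depth per chromosome was taken in 10 kb bins, each compared with autosomal bins of like GC content in 20 classes, leaving out chromosomes 8 and 11 as a reference. The spread given with it is the SD over segments of 5 Mb within 1 library.

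Gene-based results that had been planned were not computed: the share of peaks near start sites, the oxidative phosphorylation and other gene lists, and the names of nearest genes. They need an mm9 gene annotation, which was not used here, and coordinates were not converted between builds. The rule for named items, fixed before the data were examined, therefore reduces to the 10 peaks with the highest authors' score, named by position. A second set of 10 peaks was chosen after the data were seen. Alternatives covered the copies of a tag, the window, the scaling, the tag position, the score threshold and the motif, and others added later are named as such in the closing section.

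The fold over peaks, the element search, the 8-mers outside peaks, the reads from fragments of like composition and the windows called by 1 rule were tested on simulated data. The fragment length, the GC-adjusted depth, the recounts, the search for mitochondrial sequence and the ranking of 8-mers at peaks were not. With 2477 simulated windows, 50 windows with a true fold of 4 gave a median of 4.21, and the intervals held the true value in 94% of them. The simulated input counts lay well above the floor of 3 tags, so folds held down by the floor were not checked. The search found 200 of 200 placed elements, in sequence with every base known. For reads from fragments of like composition, the 95% intervals held a true excess of 0 in 183 of 200 draws (91.5%) and of 0.2 in 191 (95.5%). Of 200 8-mers raised by 0.2 on the log2 scale among 32896, all 200 came first by rank. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.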

Results

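The genome-wide binding of ERRγ was examined in neurons differentiated from ES-D3 cells, a mouse embryonic stem cell line. ERRγ belongs to the estrogen-related receptors, nuclear receptors that bind an extended half-site with the core AAGGTCA. The ERRγ ChIP library held 16555611 aligned reads and the input library 17058439. After keeping 1 tag per position and strand, 14078887 ChIP tags (85.0%) and 9933816 input tags (58.2%) remained, so copies made up 14.96% of the ChIP reads and 41.8% of the input reads.

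The authors' list held 2477 ERRγ peaks. Scores ran from 11 to 95 with a median of 12, and 852 peaks (34.4%) had the lowest score. Within the authors' 116 bp intervals lay 0.242% of the kept ChIP tags (34130 tags, exact 95% interval 0.240 to 0.245%) and 0.0405% of the kept input tags (4028 tags, 0.0393 to 0.0418%). Peaks were unevenly spread over the chromosomes. Chromosome 8 carried 422 peaks (17.0%) and chromosome 11 carried 264 (10.7%), which is 36.4 and 23.6 peaks per 1000 bins of 10 kb. The other 17 autosomes had between 6.51 and 14.3 per 1000 bins, chromosome X had 5 peaks, and chromosome Y had 0. The input depth differed in the same direction. Relative to autosomes other than 8 and 11, and adjusted for GC content, it was 1.48 ± 0.116 for chromosome 8 (SD over 24 segments of 5 Mb), 1.16 ± 0.0982 for chromosome 11 (23 segments) and 0.531 ± 0.0411 for chromosome X (11 segments), against 0.941 to 1.098 for the other autosomes.

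**Figure D1:**
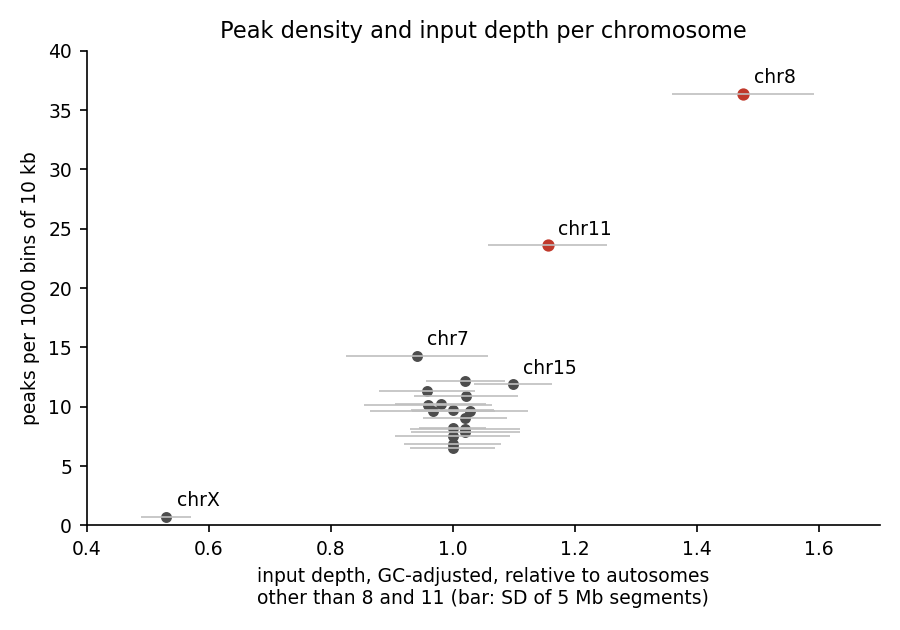
Peaks per 1000 bins of 10 kb against GC-adjusted input depth for chromosomes 1 to 19 and X. Each point is a chromosome and each bar the SD over its 5 Mb segments in the input library. Chromosome 8 lies at a depth of 1.48 with 36.4 peaks per 1000 bins, and chromosome X at 0.531 with 0.715.

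The 10 peaks with the highest authors' score, from 58 to 95, were not enriched over the deposited input. They lay in 4 places. Peaks at 24618473 to 24620772 on chromosome 1 (4 peaks), at 22444696 to 22445995 on chromosome 2 (2 peaks) and at 79649691 to 79650863 on chromosome 4 (3 peaks) were joined by 1 peak at 95540247 to 95540363 on chromosome 10. The highest-scored peak, at 24619208 to 24619324 on chromosome 1, had 208 kept ChIP tags and 162 input tags, a fold of 0.906 (0.734 to 1.12). Folds of the 10 peaks ranged from 0.649 on chromosome 10 to 1.29 on chromosome 4. None of the 10 held an AAGGTCA within 100 bp of its centre. Sequence within 2500 bp encoded fragments of the mitochondrial proteins COX2, COX3, ATP6 and ND4 at the chromosome 1 peaks, of COX1, COX2 and ND2 at the chromosome 2 peaks and of CYTB at the chromosome 4 peaks. No such fragment was found at the chromosome 10 peak. The authors' own input counts at these 10 peaks, taken in the 116 bp peak, were 7 to 29 tags. The deposited input held 60 to 203 kept tags in the wider 200 bp window, so these counts are not of like windows. Altogether 15 peaks had 20 or more kept input tags in the 200 bp window, a limit chosen after the data were seen, and their summed tags gave a fold of 0.796 (0.743 to 0.853). Summed over the remaining 2462 peaks the fold was 5.72 (5.56 to 5.89). Peaks were called in this same ChIP library, and the authors' ChIP count was at least 4.2 times their input count at every peak. The 2462 were also set apart by their input tags, so this fold describes selected windows and is not a separate check of enrichment.

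Among peaks without such input, the 10 with the highest scores (39 to 56), chosen after their values were seen, had 52 to 73 kept ChIP tags and 0 to 5 input tags. The highest of them, at 98412349 to 98412465 on chromosome 8, had 73 ChIP tags and 5 input tags, a 10.3-fold ratio (4.22 to 32.7), and a second peak of this set lay close to it at 98411525 to 98411641, with 61 and 4 tags (10.8-fold, 3.99 to 40.8). At 149610648 to 149610764 on chromosome 4 there were 72 ChIP tags and 1 input tag (50.8-fold, 8.83 to 2034), and at 47296474 to 47296590 on chromosome 8 there were 71 and 1 (50.1-fold, 8.71 to 2006). The peaks at 90687067 to 90687183 and 65253124 to 65253240 on chromosome 2 had 69 and 62 ChIP tags with 1 and 2 input tags. Neither the peak at 31822615 to 31822731 on chromosome 17 nor that at 109723672 to 109723788 on chromosome 4 had an input tag, and with the input set to the floor of 3 tags their folds were 13.4 and 14.8. Against the same floor, the 50.8-fold and 50.1-fold ratios above became 16.9 and 16.7. Among these 10 peaks, an AAGGTCA lay within 100 bp of the centre at 3: GGAAAGGTCACT at 149610651 to 149610662 on chromosome 4, GGCAAGGTCAGC on the minus strand at 90687113 to 90687124 on chromosome 2, and GCCAAGGTCATG at 98411518 to 98411529 on chromosome 8.

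**Figure D2:**
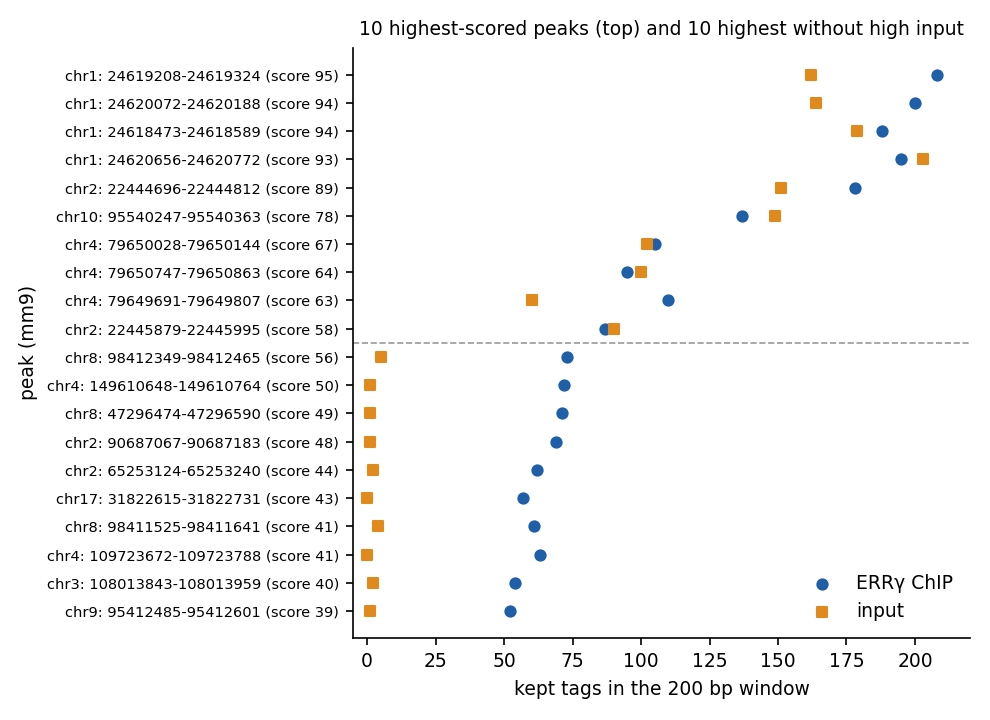
Kept tags in the 200 bp window (x axis) of the ERRγ ChIP (circles) and the input (squares) at single peaks in mm9 (y axis). Above the dashed line are the 10 peaks with the highest authors' score, where input tags number 60 to 203, and below it the 10 highest-scored peaks without high input, with 0 to 5 input tags.

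Over all peaks the median ChIP to input fold was 3.29, with a median of 15 ChIP and 2 input tags per window. The floor of 3 tags held the fold down at 1658 peaks (66.9%), of which 464 had 0 input tags. The authors' score follows the ChIP tags at a peak, so the folds by score are not a separate check of it. Leaving out the 15 high-input peaks, summed tags gave 4.31-fold (4.10 to 4.53) at the 852 peaks of score 11, 6.69-fold (6.22 to 7.20) at the 386 peaks of score 15 to 18 and 17.4-fold (13.7 to 22.5) at the 32 peaks above 30. With all deposited tags in place of kept ones the median was 5.15. The floor stayed at 3 tags in that larger input total, so the rise does not by itself show stronger enrichment.

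The ERR response element TNAAGGTCA lay within 100 bp of the centre of 196 peaks (7.91%, 6.88 to 9.05%), against 10 windows (0.404%) centred 1 kb before and 12 (0.484%) centred 1 kb after. Per covered position, sites were 7.72 times as frequent at peaks as in the windows 1 kb away (4.96 to 12.6). The share fell to 4.804% for TCAAGGTCA and was 22.4% for the core AAGGTCA. Sites were then split by the base before the core, a split made after the data were seen. Relative to windows 1 and 5 kb away, sites with C before the core were 12.3 times as frequent at peaks (9.03 to 17.2, 380 sites) and those with G 5.80 times (4.06 to 8.47, 155 sites), while A gave 2.34 (1.45 to 3.82) and T gave 1.62 (0.815 to 3.25, 20 sites). With C in place, the base in front of it could be C (14.3 times, 8.39 to 26.2), T (14.7 times, 8.31 to 28.4), G (11.7 times, 5.58 to 28.2) or A (6.16 times, 2.93 to 14.5), and all these intervals overlap. Reads outside peaks, described below, did set T in front of the C above A and G.

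Of 7062 8-mers found at 20 or more peaks, CAAGGTCA ranked first by its excess over 8-mers of the same GC and CpG counts, divided by its counting error. It lay at 357 peaks (14.4%, 13.1 to 15.9%). Its share rose from 9.39% (7.52 to 11.5%) of peaks with score 11 to 28.6% (22.5 to 35.3%) of those with scores 19 to 30. Sites were densest at the centre, with 164 per 100 kb of covered sequence within 20 bp of it, 30.4 from 60 to 100 bp and 10.2 from 200 to 500 bp. ChIP reads on the motif's own strand began mostly before it and those on the other strand after it, at up to 31.6 and 30.9 RPM per 20 bp (kept reads scaled to library size, summed over peaks), and input reads stayed between 1.61 and 4.73 RPM. Of the 24 single-base variants of CAAGGTCA, 5 had a ratio of peaks to windows away whose interval lay above 2: GAAGGTCA (5.41 times), CAAGGACA (5.19), CAAGGGCA (4.41), CAAGGTGA (3.62) and CAAGGTCG (10.2). The last of these holds a CpG and was present at 55 peaks. CATGGTCA (0.592, 0.294 to 1.13) was not detectably more frequent at peaks.

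**Figure D3:**
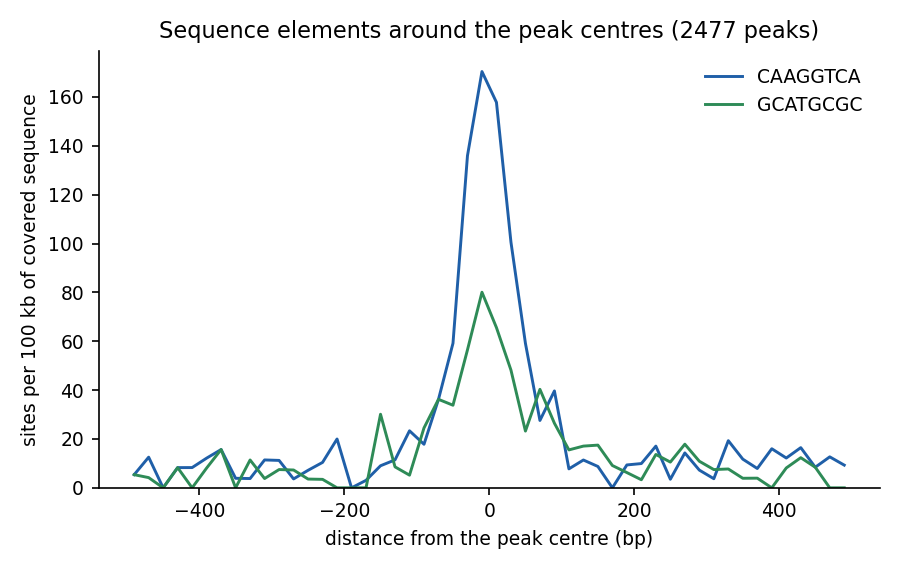
Sites per 100 kb of covered sequence (y axis) in 20 bp steps of distance from the peak centre (x axis, bp) for CAAGGTCA and GCATGCGC at 2477 peaks. Both rise towards the centre, CAAGGTCA to 164 per 100 kb within 20 bp and GCATGCGC to 72.8. GCATGCGC overlaps its own reverse complement in the full palindrome, which then counts more than once. Within 100 bp there were 204 sites of it at 127 peaks, against 380 sites of CAAGGTCA at 357 peaks.

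**Figure D4:**
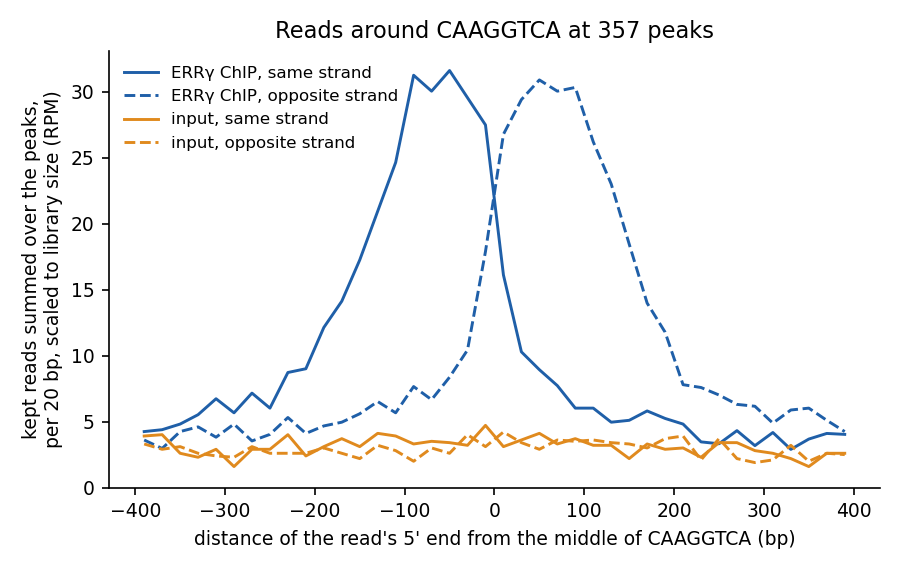
Kept reads per 20 bp scaled to library size (RPM, y axis), summed over 357 peaks, by the distance of the read's 5′ end from the middle of CAAGGTCA (x axis, bp), for the ERRγ ChIP and the input and for both strands relative to the motif. The ChIP curves of the strands peak on either side of the motif at 31.6 and 30.9, and the input curves stay between 1.61 and 4.73.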

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

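Some tests were chosen after the values they measure, or values close to them, had been seen. They are those of sequence around the high-input peaks, of the settings behind the authors' input counts and of GC content on chromosome 8. Those of AAGGTCA at GCATGCGC peaks and of GCATGCGC in reads outside peaks belong to them too. The last gave the same value for both explanations it was set against.

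A signal of the half-site was present in reads that no peak covers. In the 13968980 ChIP and 9890991 input reads more than 1 kb from any peak, CAAGGTCA occurred in 37913 ChIP and 21458 input reads. The log2 ratio lay 0.29 above the median of 8-mers with the same GC and CpG counts (SE 0.0123 from counting alone), the first rank of 32887 8-mers by excess divided by SE. It was above 0 on 20 of 20 chromosomes examined (1 to 19 and X). The 16 9-mers ending in the core lay 0.23 to 0.36 above their classes with C before the core, 0.12 to 0.24 with G, 0.02 to 0.12 with A and 0.05 to 0.13 with T, and with A or T the intervals of GAAAGGTCA, CAAAGGTCA and TTAAGGTCA lay above 0. TCAAGGTCA (0.36, 0.32 to 0.41) lay clear of ACAAGGTCA (0.23, 0.17 to 0.28) and GCAAGGTCA (0.25, 0.19 to 0.31). Its interval met that of CCAAGGTCA (0.27, 0.23 to 0.32). TGAAGGTCA (0.24, 0.19 to 0.29) lay clear of AGAAGGTCA (0.12, 0.07 to 0.17) and GGAAGGTCA (0.12, 0.07 to 0.18), but not of CGAAGGTCA (0.18, 0.04 to 0.31).

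Chromosomes 8 and 11 held more peaks per length than the others. Windows of 116 bp with at least 11 kept tags and 4 times the local density, called by 1 rule on every autosome, numbered 45.1 per 1000 bins on chromosome 8 and 31.02 on chromosome 11, against 9.85 to 19.2 on the other autosomes. After the ChIP tags of chromosome 8 were thinned to the depth of the other autosomes, 10.4 windows per 1000 bins remained (9.14 to 11.5 over 20 draws), consistent with extra copies of chromosome 8 in these cells that lift background and weak sites over a fixed tag threshold. GC content alone is argued against by the GC-adjusted input depth of 1.48. For chromosome 11, thinning left 18.7 windows (17.5 to 19.8), and whether depth alone accounts for its peaks cannot be told apart from a richer chromosome, since the draws straddle the highest other value of 19.2.

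The 15 high-input peaks, with a summed fold of 0.796, lay in 8 regions. Sequence within 2500 bp encoded a fragment of a mitochondrial protein in 4 of them, including ND5 on chromosome 13. A list of mitochondrial rRNA sequences was added after that count was seen. It raised the count to 6 of 8 regions (75%), with 16S rRNA on chromosomes 7 and 9. No such sequence was found in the regions on chromosomes 10 and 12. The 6 regions hold 13 of the 15 peaks, against 1 of 2462 other peaks with such sequence. Mitochondrial reads placed on nuclear copies of mitochondrial DNA are therefore a candidate source. The authors' input counts were higher here too, with 254 tags at the 15 peaks and 2030 at the other 2462, but over 48 settings of window, shift and copies at most 31.9% of peaks had an input count equal to the recount from the deposited input (correlation 0.715, or 0.111 without the 15 peaks), whereas 93.1% did for the ChIP count, which argues against a mere difference in counting. A source library of cells without the gain of chromosome 8 is argued against too, since the authors' input counts per peak were 1.46 times as high on chromosome 8 as on other autosomes (1.31 to 1.62). Which input tags the authors counted stays open, and ERRγ binding at these places was not tested beyond the fold.

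The sequence GCATGCGC, part of the palindrome that the transcription factor NRF1 is known to bind, lay at 127 peaks (5.13%, 4.29 to 6.07%). In reads outside peaks its log2 ratio of ChIP to input was compared with that of reads from fragments of like GC and CpG content. The ratio lay 0.25 (0.18 to 0.32) above theirs. All other sequences compared in this way lay above 0 as well. They were GCCCCGCC (0.17, 0.12 to 0.22), CGCAGGCG (0.29, 0.19 to 0.39) and GCCTGCGC (0.088, 0.022 to 0.15). TGACGTCA (0.12, 0.04 to 0.19) and CAAGGTCA (0.31, 0.28 to 0.33) were the others. No control sequence was among them, so composition of the 122 bp fragments that the matching left over is not excluded. For the same reason the comparison cannot decide on open chromatin equally rich in the ChIP and the input. GCATGCGC sites did not lie where half-sites are common. Of GCATGCGC peaks, 0.787% held CAAGGTCA (0.0199 to 4.31%) against 15.2% of other peaks, and 5.51% held the core AAGGTCA (2.24 to 11.03%) against 23.4% (21.7 to 25.2%). The summed fold at GCATGCGC peaks without CAAGGTCA was 0.840 times that of CAAGGTCA peaks (0.724 to 0.975), but peaks with neither sequence reached 0.848 times, so this fold does not set GCATGCGC peaks apart from called peaks at large, and open chromatin that is rich in the input, though less than in the ChIP, cannot be told apart from binding by it. Binding at NRF1-type sites and places that enrich with any antibody stay open as well. Neither was tested, because no library with a control antibody was analysed here.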

How the results depend on the processing

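Of 25 alternatives, 12 were added after the data were seen (those without high-input peaks or without chromosomes 8 and 11, summed tags, 4-fold with no floor and CAAGGTCA). The count of 2477 peaks fell to 591 at 4-fold and 54 at 8-fold over input in kept tags. Without the floor of 3 input tags, 1760 peaks passed 4-fold in kept tags, so the floor accounts for most of the fall at 4-fold, and 2012 passed with all tags in the authors' interval and no floor. The median fold of 3.29 was 5.15 with all tags, 3.53 in 500 bp, 3.30 with scaling by bins without a peak, 3.998 for the higher-scored peaks, 3.06 for unmoved 5′ ends and 4.56 from summed tags. With all tags the floor stayed at 3 while the input total rose from 9933816 to 17058439. The ChIP and input shares in peaks, which use no floor, were 0.242% and 0.0405% of kept tags and 0.252% and 0.0421% of all tags. The value of 5.15 is therefore no sign of stronger enrichment with copies left in. The share of ChIP tags in peaks (0.242%) was 0.252% with all tags and 0.448% in 500 bp. It was 0.234% without high-input peaks and 0.178% without the peaks of chromosomes 8 and 11. For these last values the total still held the tags of all chromosomes, so leaving out peaks could only lower the share. The share of peaks with an ERR response element (7.91%) was 4.804% for TCAAGGTCA, 22.4% for AAGGTCA, 14.4% for CAAGGTCA, 6.02% within 50 bp, 9.53% for the higher-scored peaks and 9.16% without chromosomes 8 and 11. Counts were compared within 1.5 times 2477, other values by the 95% interval of the main value, which has no width for the median fold, so small changes of the median count as changes. By these rules 7 alternatives lay within the limits. Causes of the other changes were not tested. The 11 settings planned for start sites and gene lists were not run, as no mm9 annotation was used. No paired analysis was possible because each group has 1 library.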

Other observations

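Peaks with GCATGCGC and peaks with CAAGGTCA formed nearly separate sets. Within 100 bp of the centre 357 peaks held CAAGGTCA, 127 held GCATGCGC and 1 held both, leaving out peaks with high input. Sequence at CAAGGTCA peaks was 55.2% GC with a CpG ratio (observed over expected) of 0.475, and at GCATGCGC peaks 65.4% and 0.918. Among peaks with 5 or more CpG in the window, CAAGGTCA lay at 1 of 125 with GCATGCGC (0.8%, 0.0203 to 4.38%) and at 178 of 1383 without it (12.9%, 11.1 to 14.8%). By score, GCATGCGC lay at 4.46% (3.18 to 6.07%) of peaks with score 11, 3.94% (2.43 to 6.03%) with 12, 7.05% (4.93 to 9.72%) with 13 to 14, 6.22% (4.02 to 9.11%) with 15 to 18, 4.93% (2.39 to 8.87%) with 19 to 30 and at 1 of 32 peaks above 30, with overlapping intervals. The share of CAAGGTCA was higher in each class than in the one before, though intervals of neighbouring classes overlapped too. Its interval at score 11 (7.52 to 11.5%) lay below that at scores 19 to 30 (22.5 to 35.3%).

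Another element without AAGGTCA was TGACGTCA, the site bound by CREB and ATF factors, present at 47 peaks (1.90%, 1.397 to 2.52%). It was picked after the data were seen, and other 8-mers with a CpG lay at more peaks, such as GCCCCGCC at 203 and GCCTGCGC at 179. Per covered position TGACGTCA was 5.50 times as frequent at peaks as 1 kb away (2.47 to 14.4, 7 sites away) and 31.04 times as frequent as 5 kb away (5.31 to 1252, 1 site away). These ratios were not adjusted for composition, and the CpG ratio was 0.610 at peaks against 0.337 and 0.358 at 1 kb before and after. In reads outside peaks the log2 ratio of TGACGTCA lay 0.19 above 8-mers of its class (SE 0.0354). Against reads from fragments of like GC and CpG content it lay 0.12 above (0.04 to 0.19).

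The share of peaks with an element was also taken by chromosome. TNAAGGTCA lay at 4.27% of the chromosome 8 peaks (2.55 to 6.66%), 5.30% of the chromosome 11 peaks (2.93 to 8.74%) and 9.07% of the peaks on the other 17 autosomes (7.78 to 10.5%). For CAAGGTCA the shares were 11.4% (8.51 to 14.8%), 12.9% (9.09 to 17.5%) and 15.3% (13.6 to 17.0%), with overlapping intervals.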
